A study of Macaca fascicularis with 3 samples.

How the data were processed

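The 3 libraries were 10x Genomics Chromium 3' v3.1 single-cell libraries of polyA RNA, 1 for each stage of the mouse ovarian somatic cells (E13.5, E14.5 and E15.5). The deposited files hold raw UMI counts per gene and barcode for 26017 monkey features, made by the authors with Cell Ranger 6.0.1 per the file headers and already reduced to called barcodes. The genome build and the annotation are not given in the sources used here. The features include 0 named EGFP or tdTomato and 0 named XIST, and no mouse genes. Of 9282 features with LOC names, 669 were given a symbol through their gene number.

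The deposited barcodes numbered 2807, 1565 and 3455 in E13.5, E14.5 and E15.5, with 44762884, 30607553 and 70850640 UMIs. Barcodes with over 20% mitochondrial UMIs (92, 69 and 123) and those with fewer than 1000 UMIs (323, 202 and 186) were removed. This left 2392, 1294 and 3146 barcodes with medians of 7054.5, 11218 and 7702 UMIs. The germ cells used in the comparisons held 31404570, 24034932 and 56163168 UMIs, so 3 counts, taken as the floor of detection, stand for 0.0955, 0.125 and 0.0534 CPM.

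Counts were log-normalised to 10000 and clustered jointly with scanpy 1.11.5, scikit-learn 1.9.0 and igraph 0.11.9 under Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Clustering used 2000 highly variable genes ranked within each library, 30 principal components, 15 neighbours and Leiden resolution 1 with seed 1. The genes of the gene lists were left out of it. It gave 18 clusters, which were named by hand from 126 fixed cell type markers (119 found), and some names, such as that of one late cluster, rest on small differences. The neighbour graph was chosen after the marker tables of 3 clusterings had been read: the default graph of scanpy, a shared-neighbour graph and a UMAP-type fuzzy graph. The fuzzy graph was adopted because the shared-neighbour graph merged retinoic acid-responsive and meiotic cells. Clusters of shallow germ barcodes (179, 28 and 233) and of cells led by EGR4 and PIWIL4 (4, 12 and 34) were left without a class and out of the comparisons. The remaining 559, 538 and 1100 cells are the named germ cells.

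Doublets were sought with Scrublet within scanpy at an expected rate of 5%. It predicted 6, 7 and 3 doublets (0.251%, 0.541% and 0.0954%), far under that rate, so it is taken not to have worked here, and cells were kept. A measure of RNA of both species, from 52 genes, was added after the data were seen and marked 29, 40 and 63 of the named germ cells (5.19%, 7.43% and 5.73%). Free RNA of mouse cells in germ barcodes was low by the supporting cell genes AMHR2 and WNT4, at 4.77 and 6.84 CPM in the largest late oogonia-like cluster against 378 and 518 CPM in the largest supporting cell cluster. Other markers of that list, such as KRT18 and KRT8, were higher in germ cells than in supporting cells.

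The design, most alternatives, the gene lists, the markers and the rule for named genes were fixed before the data were examined, while the neighbour graph and the alternatives that the closing section names as later choices were chosen afterwards. CPM are UMI counts scaled by the total UMIs of the cells summed. Libraries were compared as log2 ratios of CPM + 1 of summed named germ cells, and within each class with at least 50 cells in both libraries. Equal weight to each class means the mean CPM of the early, late and retinoic acid-responsive classes. The meiotic class, with too few cells for that rule, was left out of it. A gene passed the size rule at 2-fold or more with at least 20 CPM in 1 library. With 1 library per stage no p-value was made between libraries. Values have exact Poisson or exact Clopper-Pearson 95% intervals. Gene lists were placed by the percentile of their median among 10000 random lists, each member replaced by 1 of the 101 genes nearest in mean expression.

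Germ classes were compared with edgeR 4.0.16 and limma 3.58.1 under R 4.3.3, on UMI counts summed per library and class (12 sums, 6 residual degrees of freedom, at least 20 cells in each), with filterByExpr, TMM, a quasi-likelihood test with the library as block, and Benjamini-Hochberg adjustment at a threshold of 0.05. Of 16264 genes past the filter, 1706 highly variable genes and markers were left out, because classes made from a gene cannot test it, and 14558 were tested. The classes still come from the same cells as the test, and the 3 libraries that serve as repeats differ in mouse stage. Lists were tested with fry, and with camera at a correlation of 0.01, adjusted over the lists of a contrast. Each gene's fold change has the standard error of the fit. DESeq2 1.42.0 served as an alternative, and figures were drawn with matplotlib 3.10.9.

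The 17 gene lists held 293 genes, 267 of them found: synaptonemal complex and cohesin, meiotic recombination, piRNA and transposon defence, DNA methylation machinery, pluripotency-associated, folliculogenesis and maternal-effect, S phase, G2 and M phase, retinoic acid signalling, BMP and SMAD targets, WNT targets, p53 targets, dissociation stress, glycolysis and hypoxia, oxidative phosphorylation, cholesterol biosynthesis, and X inactivation and dosage. The last had 1 of 5 genes found and was not tested.

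Named genes followed this rule. Between libraries these were the 10 highest and 10 lowest log2 ratios among genes with a symbol that passed the size rule with the same direction in each class, and the 2 members of each list with the largest ratio. Between classes these were the 6 highest and 6 lowest called list genes and the 5 highest and 5 lowest called genes with an average log CPM of at least 5. TFAP2C, DDX4, DAZL, SYCP3, STRA8 and ZGLP1 were always named. The text gives a part of these genes, and leaves out fold changes of genes with 0 to 3 counts in a compared sum of a library and class.

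The computations were checked on simulated data. Of 200 genes changed 4-fold between libraries among 7351, 100% passed the size rule and 0% of the others did. These counts had sampling error only, so this does not measure how far repeats of a library would vary. Of 200 genes changed 3-fold between classes among 13717, 100% were called, and 3.85% and 3.38% of the calls in the 2 contrasts concerned were false. Of 100 unchanged lists, 7 had a fry p under 0.05 and 0 after adjustment. The simulated classes were given beforehand and the genes varied independently. False calls from clustering and testing the same cells, or from correlated list genes, were therefore not covered. Clustering on UMIs drawn at random from each cell, with the others kept for the test, gave 86.3% of the named germ cells the same class. These clusters took the class that most of their cells held in the main clustering, which had used all UMIs. Their naming was therefore not independent of the tested UMIs. Alternatives covered depth, resolution, number of variable genes, scaling, pseudocount, filters, doublets, thinning, the library block, each library left out in turn, DESeq2 and splitting the UMIs of each cell between clustering and test. The closing section gives their effect.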

Results

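Single-cell RNA was measured in cynomolgus monkey germ cells derived from the embryonic stem cell line 15XRi-AGVT#7 and cultured in xenogeneic reconstituted ovaries, which are aggregates of these cells with mouse fetal ovarian somatic cells. The line carries TFAP2C-EGFP, a reporter of early germ cells, and DDX4-tdTomato, a reporter of later ones. The 3 libraries differ in the embryonic stage of the mouse ovarian cells, which was E13.5, E14.5 or E15.5, with 1 library per stage and no replicates. Reporter-positive germ cells and reporter-negative mouse cells were sorted and mixed back before loading, so the ratio of germ to mouse cells was set by the sort and the mixing. The deposited tables held 2807 barcodes with 44762884 UMIs for E13.5, 1565 barcodes with 30607553 UMIs for E14.5 and 3455 barcodes with 70850640 UMIs for E15.5. After filtering, 742, 578 and 1367 barcodes lay in germ clusters and 1650, 716 and 1779 in mouse clusters. The germ counts include shallow barcodes without a class, in which genes abundant in mouse barcodes were among the leading genes. Only monkey genes were counted, so mouse RNA was seen where its reads mapped to a monkey gene.

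The first question was how far the germ cells had advanced in each library, from TFAP2C-positive early oogonia towards meiotic prophase. Germ cells fell into 4 classes, called early oogonia-like (TFAP2C, SOX17), late oogonia-like (DDX4 and DAZL above their early level, TFAP2C below it), retinoic acid-responsive-like (STRA8, REC8, ANHX) and meiotic-like (SYCP3, SPO11). STRA8, REC8 and ANHX were the 3 of 8 fixed retinoic acid-responsive markers that were highest in the class of that name, while ZGLP1 and ZNF483 were higher in both late clusters. Of 10 late oogonia markers, 1 was highest in a late cluster. The others were highest in the meiotic cluster (4), an unnamed germ cluster (3) and the retinoic acid-responsive cluster (2). All 4 classes were present in every library, and no cluster was named oocyte-like. However, 8 of 10 oocyte markers were highest in an unnamed cluster of 50 cells led by EGR4, among them SOHLH1 at 243 CPM, JAG1 at 25.2 CPM and FIGLA at 21.8 CPM. The early class was a smaller share in E13.5 than in the other libraries, while the meiotic class had nearly the same small share in all 3 in the main clustering. The differences have no replicate check.

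Early oogonia-like cells made up 13.4% of the named germ cells in E13.5 (95% exact Clopper-Pearson interval 10.7 to 16.5, 75 of 559 cells). They made up 25.7% in E14.5 (22.0 to 29.6, 138 of 538 cells) and 24.5% in E15.5 (22.0 to 27.2, 270 of 1100 cells). Late oogonia-like cells were 48.8% (44.6 to 53.1), 45.0% (40.7 to 49.3) and 38.3% (35.4 to 41.2) in E13.5, E14.5 and E15.5. Retinoic acid-responsive-like cells were 31.5% (27.7 to 35.5), 23.4% (19.9 to 27.2) and 31.5% (28.8 to 34.4). Meiotic-like cells were 6.26% (4.40 to 8.60), 5.95% (4.10 to 8.29) and 5.64% (4.35 to 7.17), so a difference between libraries was not detectable at this depth. With cells thinned to one depth, meiotic-like cells were 3.69%, 5.12% and 5.74%, in the opposite order. Intervals here and elsewhere cover counting error only. The line between the late and the retinoic acid-responsive class moved with the clustering, and the meiotic class was not separated under 3 other clusterings. The early share stayed lower in E13.5 than in the other libraries under each clustering alternative whose shares were computed. Clusters of an alternative took the class that most of their cells held in the main clustering. They were not named anew from markers, so these alternatives are not independent of the main one. The shares were not computed for the default neighbour graph of scanpy.

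**Figure D1:**
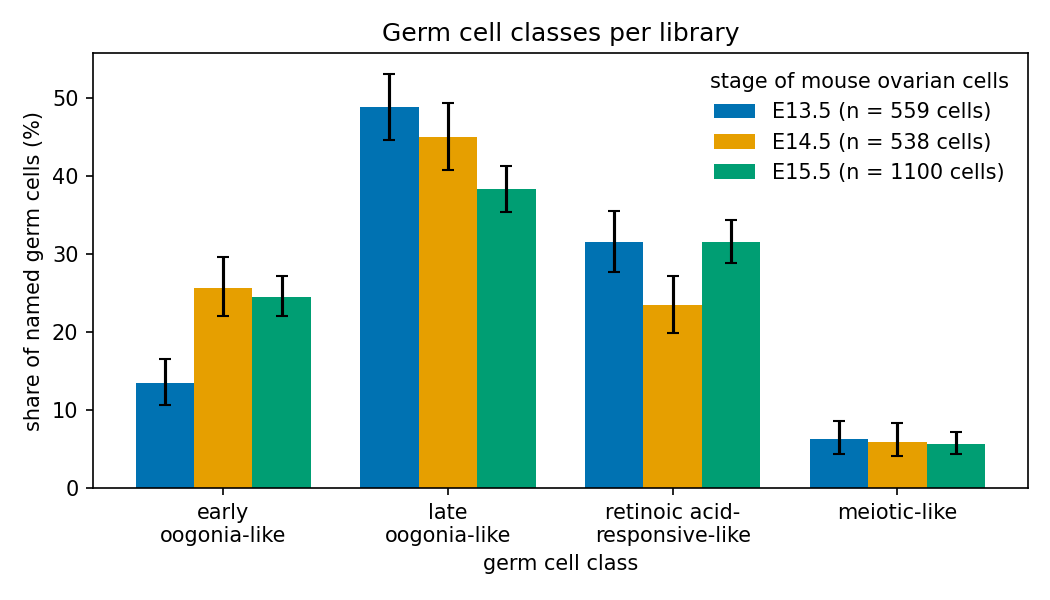
Share of each germ cell class (%) among the named germ cells of the E13.5, E14.5 and E15.5 libraries, with exact 95% binomial intervals as error bars. The early oogonia-like share was 13.4% in E13.5, 25.7% in E14.5 and 24.5% in E15.5.

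TFAP2C, a transcription factor of early germ cells, had a UMI in 37.7%, 43.1% and 45.3% of the named germ cells of E13.5, E14.5 and E15.5. The germ cell RNA-binding genes DDX4 and DAZL were near saturation: DDX4 had one in 94.1%, 92.8% and 93.6%, and DAZL in 545 of 559 E13.5 cells and in 96.8% and 98.5% of the E14.5 and E15.5 cells. SYCP3, which encodes a synaptonemal complex protein, had one in 90.9%, 89.0% and 89.8%. STRA8, the retinoic acid-induced gatekeeper of meiosis, had one in 57.6%, 42.0% and 53.9%, and ZGLP1, a BMP-induced regulator of oogenic fate, in 69.2%, 61.7% and 67.2%. Median depths of the germ cells were 55044, 42424.5 and 48297.5 UMIs. In mouse barcodes, at median depths of 6460, 6673.5 and 5298 UMIs, DAZL had a UMI in 5.76%, 3.91% and 8.26%, and SYCP3 in 1.58%, 1.82% and 4.05%. Whether these were free RNA, mouse reads on a monkey gene or barcodes of both species was not tested. Thinned to 23000 UMIs per cell, STRA8 had a UMI in 42.7%, 31.0% and 41.3% of the named germ cells with at least that depth.

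Germ cells of E14.5 differed from those of E13.5 in few genes, led by TKTL1, which encodes a transketolase-like enzyme of sugar metabolism. POU5F1, TCL1B, DNMT3L, KHDC3L and GPHA2, which were highest in early oogonia-like cells, were also higher in E14.5, where that class was a larger share. CTSD, which encodes a lysosomal protease, the endoplasmic reticulum gene CRELD2 and the matrix enzyme gene LOXL1 were lower. Of 7421 genes at 20 CPM (UMI counts scaled to equal library totals) or more, 18 were at least 2-fold higher and 18 at least 2-fold lower. The median log2 ratio of all these genes was -0.13, and -0.016 with TMM factors and 0.0019 with DESeq2 size factors, so small changes are read against it. The count of higher genes rose with DESeq2 size factors and fell with equal weight to each class, with values in the closing section.

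TKTL1 was 3.25 CPM in E13.5 (95% exact Poisson interval 2.65 to 3.94), 36.5 CPM in E14.5 (34.1 to 38.99) and 26.0 CPM in E15.5 (24.7 to 27.3). Its log2 ratio of E14.5 over E13.5 was 3.14, which is 8.83-fold, and it was 3.77 in the late and 3.15 in the retinoic acid-responsive class. In the early class TKTL1 had no UMI in E13.5 and 1.91 CPM in E14.5, so its log2 ratio there, 1.54, rests on the pseudocount. In the meiotic class it was 27.9, 108 and 216 CPM in E13.5, E14.5 and E15.5. GPHA2, a glycoprotein hormone subunit gene, was 39.2 and 117 CPM, with a log2 ratio of 1.56. POU5F1, a pluripotency gene and one of the markers that named the early class, was 177 and 453 CPM (log2 ratio 1.35). KHDC3L, a maternal-effect gene, had a log2 ratio of 1.18, IFITM1 of 1.10, the antiviral deaminase gene APOBEC3H of 1.09, TCL1B of 1.05 and the methyltransferase cofactor DNMT3L of 1.02. When each class had equal weight, the log2 ratios of these 7 genes from GPHA2 to DNMT3L were between 0.23 and 0.79. LGALS1 was 107 and 227 CPM (log2 ratio 1.07), but mouse barcodes held 1581 and 1498 CPM of it, so mouse RNA can enter its value. The lower genes included LOXL1 at 28.1 and 8.61 CPM (log2 ratio -1.60), CTSD at 51.5 and 20.9 CPM (-1.26), ZNF544 (-1.09), CRELD2 at 33.8 and 15.6 CPM (-1.07) and PITHD1 (-1.05). LOXL1 also differed in mouse barcodes, at 25.6 and 8.57 CPM. PPIA (-1.70), H3F3A (-1.64) and RPL32 (-1.21) were lower too, but each has near-identical copies in the genome between which reads can be shared.

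Among the gene lists, piRNA and transposon defence and the WNT targets lay lowest in pooled germ cells of E14.5 relative to E13.5, and the p53 targets highest, with values that differed between classes. The piRNA list, whose genes silence transposons in germ cells, had a median log2 ratio of -0.32, at percentile 0.50 of 10000 random lists matched for expression, with TDRD1 at 129 and 85.5 CPM. The WNT targets had a median of -0.40 (percentile 0.730), with LEF1 at 20.1 and 12.4 CPM, and the retinoic acid signalling list one of -0.34 (2.06), with CRABP2 at 109 and 74.9 CPM. With equal weight to each class these medians were -0.24 for the WNT targets and -0.20 for retinoic acid signalling. BMP and SMAD targets had -0.21 (3.78), with MSX1 at 169 and 103 CPM, DNA methylation machinery -0.27 (2.89), and the G2 and M phase list -0.19 (3.75), with CENPE at 157 and 113 CPM. The p53 targets had 0.073 (99.2), with PHLDA3 at 28.1 and 52.7 CPM and PMAIP1 at 36.8 and 60.8 CPM. Within early, late and retinoic acid-responsive cells the p53 targets had 0.27 (100), -0.072 (61.0) and 0.056 (93.8), and the piRNA list -0.63 (0.145), -0.18 (5.05) and -0.11 (37.2). In late and retinoic acid-responsive cells the WNT targets had -0.084 (45.9) and -0.44 (0.0800), and retinoic acid signalling -0.0052 (83.3) and -0.14 (25.4). BMP and SMAD targets had -0.037 (59.9) in retinoic acid-responsive cells, and DNA methylation machinery -0.067 (45.3) in late cells. The pluripotency-associated list had 0.0044 (97.7), but -0.084 with equal weight to each class and -0.27 (2.20) within early cells, where 9 of 11 members were lower. Cholesterol biosynthesis had 0.012 (97.4) and the synaptonemal complex and cohesin list 0.032 (96.8), but in retinoic acid-responsive cells they had -0.16 (15.8) and -0.17 (15.0). Nearer the middle were glycolysis and hypoxia at -0.0063 (89.4), folliculogenesis and maternal-effect at -0.026 (81.3), meiotic recombination at -0.11 (66.9), dissociation stress at -0.099 (64.6), S phase at -0.093 (60.7) and oxidative phosphorylation at -0.11 (22.1). Random lists do not carry the correlation among a list's genes, and with this many lists some lie near an end by chance.

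**Figure D2:**
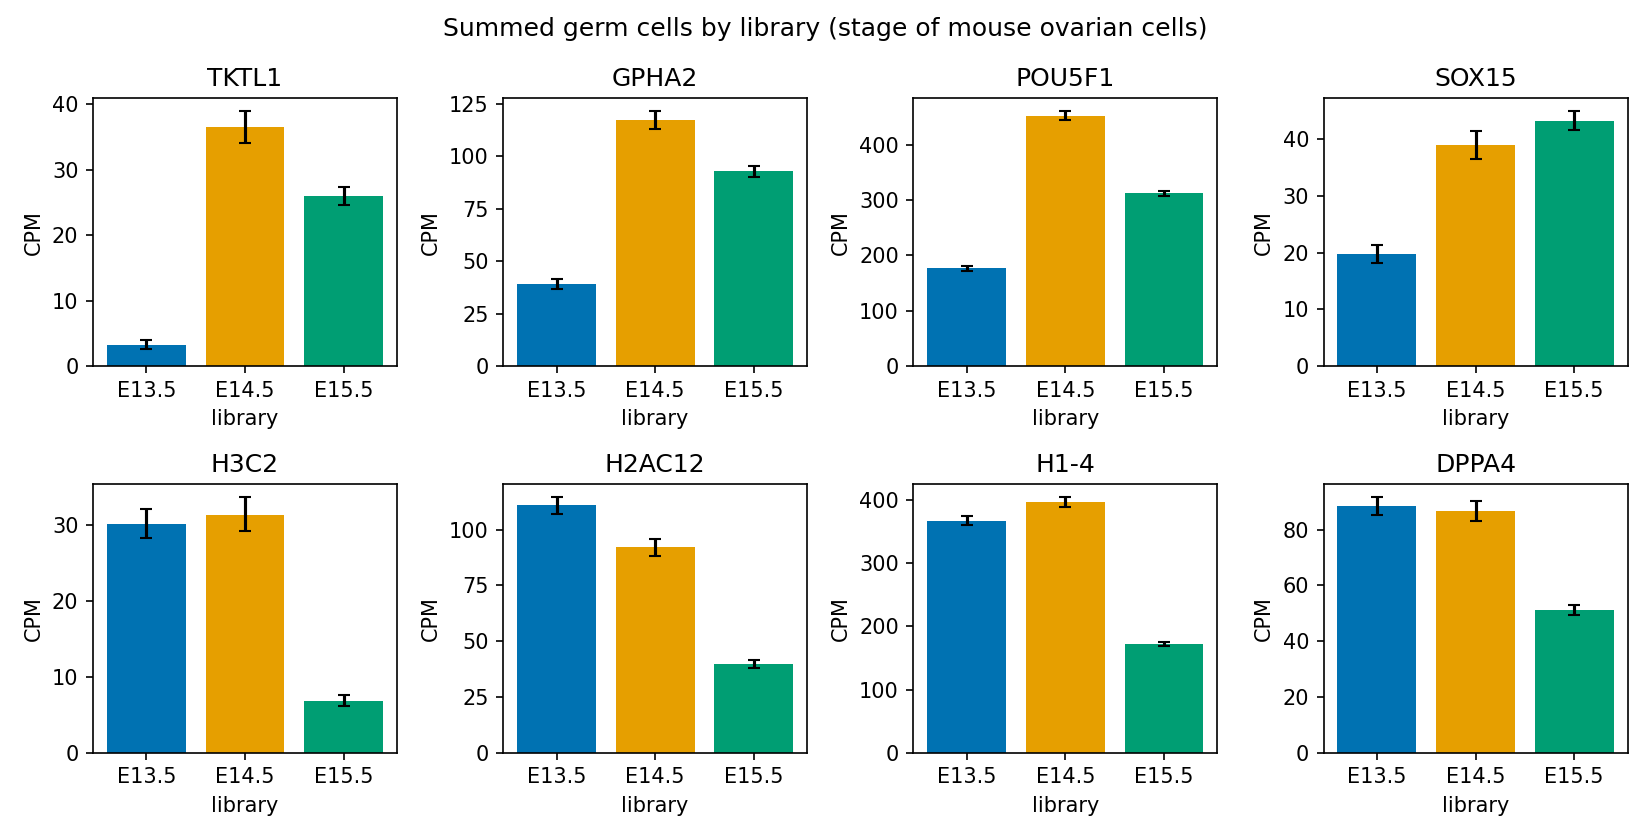
CPM of named genes in the summed named germ cells of the E13.5, E14.5 and E15.5 libraries, with exact Poisson 95% intervals as error bars. TKTL1 was 3.25, 36.5 and 26.0 CPM, and H3C2 was 30.2, 31.4 and 6.87 CPM.

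Germ cells of E15.5 also had more TKTL1 and GPHA2 RNA than those of E13.5, and less RNA of replication-dependent histone genes, whose products package newly made DNA. SOX15, a marker that named the early class, and PLAU, the urokinase gene, were higher. Of 7534 genes, 5 were at least 2-fold higher and 14 at least 2-fold lower. The log2 ratio was 2.67 for TKTL1 (6.35-fold), with 0.70, 1.09 and 3.36 in the early, late and retinoic acid-responsive classes, 1.22 for GPHA2, 1.09 for SOX15 and 1.01 for PLAU. With equal weight to the early, late and retinoic acid-responsive classes, 0 genes passed the size rule as higher. TKTL1 was then under the minimum of 20 CPM, though its ratio stayed above 2-fold. The meiotic class, where TKTL1 in E15.5 was above its pooled value, was left out of this weighting. H3C2 was 30.2 CPM in E13.5 and 6.87 CPM in E15.5 (log2 ratio -1.99), H2AC12 was 111 and 39.7 CPM (-1.46), H2AC1 was 25.9 and 8.94 CPM (-1.44) and H1-4 was 368 and 172 CPM (-1.09). H1-4 differed in mouse barcodes as well, at 244 and 112 CPM. The mitochondrial gene ATP8 (-1.11), the cancer-testis gene CT45A10 (-1.10), FAM98B (-1.08), the ribosomal protein gene RPS27 (-1.07), whose reads can be shared with copies, and WWOX (-1.01) were also lower. The share of mitochondrial UMIs in germ cells was 6.90%, 7.03% and 9.13% in E13.5, E14.5 and E15.5, so it was higher in E15.5 while ATP8 was lower.

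The G2 and M phase list had a median log2 ratio of -0.23 in E15.5 over E13.5 (percentile 0.150), with CENPE at 157 and 96.3 CPM, but near 0 with equal weight to each class. DNA methylation machinery had -0.31 (0.430), meiotic recombination -0.17 (1.34), retinoic acid signalling -0.24 (1.69) with CRABP2 at 109 and 62.3 CPM, and piRNA and transposon defence -0.16 (7.35) with TDRD1 at 129 and 75.7 CPM. The retinoic acid signalling median was nearer 0 within classes, at -0.047 (41.4) in late and -0.18 (6.46) in retinoic acid-responsive cells. Meiotic recombination had -0.15 (4.40) in early and -0.18 (1.29) in late cells but 0.031 (78.9) in retinoic acid-responsive cells, and the G2 and M phase list had 0.12 (98.8), -0.16 (1.62) and 0.017 (69.4) in these classes. The synaptonemal complex and cohesin list had 0.10 (96.7), with TEX12 at 21.7 and 30.6 CPM, but -0.056 (37.7) in late cells, S phase 0.043 (97.0) and folliculogenesis and maternal-effect 0.26 (99.2), a median of only 3 genes at 20 CPM or more (2 above and 1 below 0), with CPEB1 at 132 and 177 CPM.

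Between E15.5 and E14.5, H3C2 had the largest log2 ratio in size among the genes named here. Of 7371 genes, 10 were at least 2-fold higher and 14 at least 2-fold lower in E15.5. The count of higher genes fell with TMM factors and with DESeq2 size factors, with values in the closing section. H3C2 had a log2 ratio of -2.04, H1-4 of -1.20, H2AC12 of -1.19 and H2AC1 of -1.17. LOXL1 (1.28), RBP4, a retinol carrier gene at 8.74 and 22.0 CPM (1.24), CRELD2 (1.08) and H3F3A (1.05) were higher in E15.5. The pluripotency-associated list had a median of -0.16 (percentile 0.0700), with DPPA4 at 86.7 and 51.1 CPM, with -0.27 (0.0250) in late and -0.43 (0) in retinoic acid-responsive cells but 0.035 (34.5) in early cells, and the p53 targets had -0.11 (1.11), with PMAIP1 at 60.8 and 40.9 CPM. S phase had 0.16 (99.4), with MCM5 at 111 and 151 CPM, and the WNT targets 0.32 (96.9), with 0.12 (68.7) in late cells.

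The second question was which genes differ from class to class, tested with the 3 libraries as repeats. The order of the classes, from early to meiotic, was fixed beforehand and was not tested. Rose and fell mean higher and lower in the later class of a contrast. From early to late oogonia-like cells, most genes of the pluripotency and glycolysis lists fell and most of the synaptonemal complex and BMP lists rose, as did 15 of 25 meiotic recombination genes (4 fell) and 10 of 17 retinoic acid signalling genes (2 fell). No list call of this contrast held with an estimated correlation, the lowest value being an adjusted p = 0.346 with an estimated correlation. MSX1, a BMP-induced homeobox gene, CRABP2, which carries retinoic acid, the piRNA gene TDRD7 and TEX15 rose, as did FZD7, HOXB4 and HOXA3. DNMT3L, TCL1B, KHDC3L, ACTG2, FERMT1, DPEP2 and RAB43 fell. Of 14558 genes tested, 4483 were higher and 4745 lower in the late class, and 2179 and 1726 of them differed at least 2-fold.

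MSX1 was 133 ± 18.6 CPM in late and 3.34 ± 1.38 CPM in early oogonia-like cells (mean ± SD over 3 libraries), a log2 fold change of 4.67 ± 0.21 (SE) with an edgeR adjusted p of 1.64e-15 and the same direction in 3 of 3 libraries. DNMT3L was 3.24 ± 1.01 and 85.8 ± 5.75 CPM, a log2 fold change of -5.19 ± 0.16 (adjusted p 4.79e-18, 3 of 3 libraries). The log2 fold change was 4.37 for FZD7, 3.67 for HOXB4, 3.66 for CRABP2, 3.60 for HOXA3, 3.23 for TDRD7 and 3.07 for TEX15. It was -6.27 for ACTG2, -4.33 for FERMT1, -4.11 for both TCL1B and DPEP2, -4.02 for RAB43, -3.49 for KHDC3L and -2.83 for NODAL. These genes had the same direction in 3 of 3 libraries.

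In the late class 14 of 18 BMP and SMAD targets were higher and 3 lower (15 and 3 adjusted over the list alone), with a median log2 fold change of 0.89 (fry adjusted p 0.000976), but their camera test gave an adjusted p = 0.346 with an estimated correlation. The synaptonemal complex and cohesin list had 8 of 11 higher and 0 lower (9 and 0 adjusted over the list alone; median 1.25, fry adjusted p 0.000274), piRNA and transposon defence 12 of 18 higher and 3 lower (median 0.92, 0.000852) and retinoic acid signalling 10 of 17 higher and 2 lower (11 and 3 adjusted over the list alone; median 0.62, 0.000852). WNT targets had 7 of 9 higher and 2 lower (median 1.56, 0.000502), meiotic recombination 15 of 25 higher and 4 lower (16 and 6 adjusted over the list alone; median 0.74, 0.000976) and the G2 and M phase list 16 of 19 higher and 1 lower (17 and 1 adjusted over the list alone; median 0.67, 0.0144). One of the 2 late clusters was led by mitosis genes although this list was left out of the clustering, so the G2 and M phase result rests partly on how the class was made. Glycolysis and hypoxia had 16 of 19 lower and 2 higher (median -0.90, 0.000963), pluripotency-associated genes 14 of 18 lower and 2 higher (median -1.29, 0.00222), p53 targets 10 of 14 lower and 1 higher (median -0.91, 0.000976) and cholesterol biosynthesis 10 of 15 lower and 1 higher (median -0.64, 0.00135). For DNA methylation machinery the median of -0.27 and the direction of fry (up, 0.00466) differed in sign, and for oxidative phosphorylation the median of 0.023 and the mean of -0.093 did (fry down, 0.0405), and camera called neither of these 2. S phase, folliculogenesis and dissociation stress had fry adjusted p values of 0.510, 0.895 and 0.400.

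**Figure D3:**
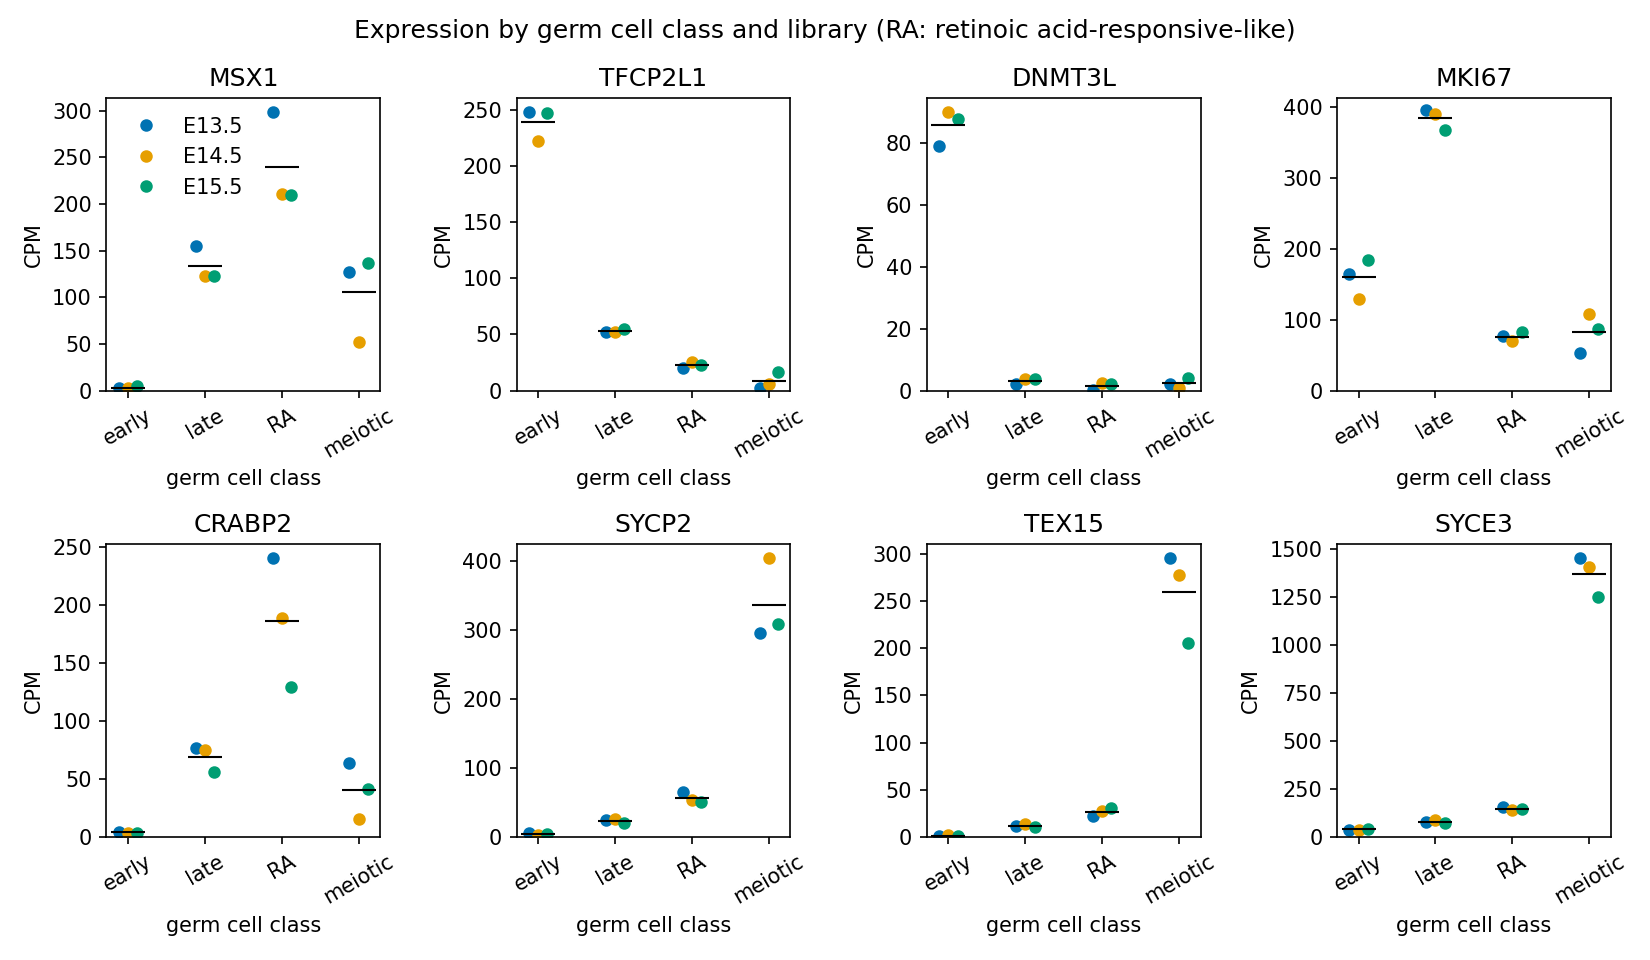
CPM of named genes in the 4 germ cell classes; points are the E13.5, E14.5 and E15.5 libraries and black bars their mean, and RA stands for retinoic acid-responsive-like. MSX1 had a mean of 3.34 CPM in early and 133 CPM in late oogonia-like cells.

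From late oogonia-like to retinoic acid-responsive-like cells, mitosis genes fell, some meiosis genes rose and most of the retinoic acid signalling list rose. No list call of this contrast held with an estimated correlation. The mitotic regulators UBE2C, CDC20, NUSAP1, KIF20A, PLK1, AURKB and MKI67 fell. TEX12 and FKBP6, which act at the synaptonemal complex, the WNT effector LEF1, CRABP2, SESN3 and CXCR4 rose. In this contrast 2542 genes were higher and 2899 lower. These counts fell to 1477 and 1688 without the E13.5 library and to 1483 and 1884 without the E15.5 library. UBE2C was 53.9 ± 14.6 and 326 ± 44.0 CPM, a log2 fold change of -2.75 ± 0.12 (edgeR adjusted p 6.11e-14, 3 of 3 libraries). TEX12 was 36.4 ± 3.85 and 9.17 ± 2.89 CPM, a log2 fold change of 1.82 ± 0.14 (adjusted p 5.92e-10, 3 of 3 libraries). The log2 fold change was -2.73 for CDC20, -2.64 for both NUSAP1 and KIF20A, -2.61 for PLK1, -2.57 for AURKB and -2.46 for MKI67. It was 2.69 for the piRNA gene PIWIL4, 2.12 for BOLL, 1.78 for LEF1, 1.27 for both CRABP2 and SESN3, 1.26 for CXCR4 and 1.23 for FKBP6, with the same direction in 3 of 3 libraries for each gene named here.

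In the retinoic acid-responsive class 19 of 19 G2 and M phase genes were lower (median -2.02, fry adjusted p 0.000471), as were 16 of 19 S phase genes (median -0.45, 0.000720). These 2 lists had an adjusted p = 0.174 with an estimated correlation, the lowest of this contrast. The fall in G2 and M phase genes rests partly on how the late class was made, since 1 of its 2 clusters was led by mitosis genes such as PLK1, UBE2C, CDC20 and MKI67. Retinoic acid signalling had 11 of 17 higher and 1 lower (median 0.73, 0.0152), piRNA and transposon defence 10 of 18 higher and 1 lower (median 0.48, 0.0152), synaptonemal complex and cohesin 5 of 11 higher and 3 lower (median 0.44, 0.0152), WNT targets 5 of 9 (median 0.47, 0.0492) and cholesterol biosynthesis 6 of 15 (7 adjusted over the list alone; median 0.26, 0.0366). DNA methylation machinery had 4 of 11 lower (0.0152). Camera at its preset correlation did not call synaptonemal complex and cohesin (0.0627), WNT targets (0.0666) or DNA methylation (0.229). Meiotic recombination was not called, with 10 of 25 higher and 4 lower (12 and 5 adjusted over the list alone; fry adjusted p 0.597, camera 0.0769). Pluripotency-associated genes had 10 of 18 lower and 2 higher (median -0.44). Fry did not call them (adjusted p 0.111), while camera at its preset correlation called them lower (adjusted p 0.0423). Lists called higher by fry numbered 5, and 1, 2 and 1 without the E13.5, E14.5 and E15.5 library. Each of these fits had fewer residual degrees of freedom, so lost power and dependence on a library cannot be told apart.

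From retinoic acid-responsive-like to meiotic-like cells, most genes of chromosome pairing and recombination rose, 10 of 17 retinoic acid signalling genes fell and 2 rose. No list call of this contrast held with an estimated correlation, the lowest value being an adjusted p = 0.258 with an estimated correlation. TEX15, MSH4, HORMAD2, SYCE3, TEX12, CCNE2, TEX19 and CYSTM1 rose. LIN28A, ZFP42, GCNT2, RND2, SKAP2, SH3BGRL3 and the gut hormone gene GIP fell. The meiotic class was small, with 35, 32 and 62 cells, and in E13.5 only 71.4% of its cells had a SYCP3 UMI, so it includes shallow barcodes. In this contrast 3555 genes were higher and 4040 lower. SYCE3, a central element gene of the synaptonemal complex, was 1372 ± 106 and 147 ± 9.12 CPM, a log2 fold change of 3.11 ± 0.091 (edgeR adjusted p 7.83e-18, 3 of 3 libraries). The log2 fold change was 4.71 for TEX19, 4.35 for MSH4, 4.22 for HORMAD2, 3.69 for CCNE2, 3.11 for TEX15, 2.99 for CYSTM1, 2.71 for TEX12 and 2.56 for NUSAP1. It was -2.93 for RND2, -2.55 for SH3BGRL3, -2.53 for SKAP2 and -2.26 for LIN28A, with the same direction in 3 of 3 libraries for each gene.

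Meiotic recombination had 23 of 25 genes higher in the meiotic class and 1 lower (median 1.22, fry adjusted p 5.56e-05), and synaptonemal complex and cohesin had 10 of 11 higher (median 2.46, 1.24e-05). For both, camera gave an adjusted p = 0.258 with an estimated correlation. S phase had 11 of 19 higher and 4 lower (median 0.76, 0.000148), dissociation stress 9 of 12 and 1 (median 0.90, 0.00146), piRNA and transposon defence 11 of 18 and 4 (median 0.54, 0.00146), G2 and M phase 9 of 19 and 4 (median 0.43, 0.0363) and cholesterol biosynthesis 5 of 15 and 2 (0.0107). Retinoic acid signalling had 10 of 17 lower and 2 higher (0.000373), BMP and SMAD targets 11 of 18 and 2 (12 and 2 adjusted over the list alone; median -0.91, 0.00534), WNT targets 5 of 9 and 0 (0.00146), pluripotency-associated genes 9 of 18 and 3 (0.0189), glycolysis and hypoxia 10 of 19 and 4 (0.0302), oxidative phosphorylation 8 of 16 and 2 (0.00644) and DNA methylation machinery 4 of 11 and 1 (0.00159). At its preset correlation, camera did not call pluripotency (0.174), glycolysis and oxidative phosphorylation (0.230 each), DNA methylation (0.328), WNT targets and G2 and M phase (0.0571 each) or cholesterol biosynthesis (0.0633). Lists called lower by fry numbered 7, and 3 without the E13.5 library. Lists called higher also numbered 7, and 4 without the E15.5 library.

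Meiotic-like cells differed from early oogonia-like cells in 4865 genes that were higher and 5406 that were lower. The meiosis genes SYCP2, SMC1B, MEIOC and TEX15 rose, and the pluripotency genes TFCP2L1, DPPA4 and TCL1B fell. SYCP2, an axial element gene, was 337 ± 59.0 and 3.96 ± 1.34 CPM, a log2 fold change of 5.77 ± 0.16 (edgeR adjusted p 3.91e-19, 3 of 3 libraries). The log2 fold change was 7.26 for TEX15, 5.17 for MEIOC, 4.58 for the cohesin gene SMC1B and 4.41 for KIF21A. It was -4.30 for DPPA4, with the same direction in 3 of 3 libraries for each gene. DNMT3L was 2.36 ± 1.49 and 85.8 ± 5.75 CPM, ACTG2 3.08 ± 2.68 and 148 ± 23.7 CPM, TCL1B 5.24 ± 4.79 and 161 ± 26.8 CPM and TFCP2L1 8.33 ± 7.66 and 239 ± 14.9 CPM, also in 3 of 3 libraries. Their meiotic-like values rest on 1 to 3 counts in at least 1 library, so no fold change is given. Pluripotency-associated genes had 16 of 18 lower and 1 higher (fry adjusted p 6.42e-05). Synaptonemal complex and cohesin had 10 of 11 higher (11 adjusted over the list alone; median 4.10, 2.98e-07), and an adjusted p = 0.273 with an estimated correlation, the lowest of this contrast. Meiotic recombination had 19 of 25 higher and 4 lower (4.61e-06), piRNA and transposon defence 14 of 18 and 3 (5.26e-06), dissociation stress 9 of 12 and 3 (median 1.33, 0.00112), WNT targets 5 of 9 and 2 (6 and 2 adjusted over the list alone; 0.00131) and retinoic acid signalling 6 of 17 and 4 (0.00934). Glycolysis and hypoxia had 11 of 19 lower and 3 higher (0.000141), oxidative phosphorylation 8 of 16 and 5 (9 and 5 adjusted over the list alone; 0.000363), p53 targets 8 of 14 and 4 (0.000367), DNA methylation machinery 5 of 11 and 2 (0.000440) and G2 and M phase 11 of 19 and 1 (0.00789). Of the lists in this paragraph, camera at its preset correlation called only pluripotency, synaptonemal complex and cohesin, meiotic recombination and piRNA and transposon defence. For S phase the median of -0.28 and the mean of 0.20 differed in sign (fry up, 0.256), as they did for BMP and SMAD targets, at -0.015 and 0.24 (fry up, 0.145).

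The fry test asks whether the genes of a list move, on balance, one way, and it does not compare them with other genes. Camera, which does, called 7 lists higher and 4 lower in late against early cells, 3 and 3 in retinoic acid-responsive against late, 5 and 2 in meiotic against retinoic acid-responsive, and 3 and 1 in meiotic against early, at a preset correlation of 0.01. No call held with an estimated correlation. For synaptonemal complex and cohesin in meiotic against retinoic acid-responsive cells, camera gave 5.32e-06 with the preset value and an adjusted p = 0.258 with an estimated correlation.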

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

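The tests of the early class share, of the genes higher in E14.5 and of the histone genes were chosen only after the result was seen, and the parts of the gene patterns and the conditions on mouse S phase genes and on histone genes of both species were set after a first run of those tests.

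A cluster of 50 germ cells led by EGR4 and PIWIL4 carried a signal in cells that no comparison used. It held 4, 12 and 34 cells in E13.5, E14.5 and E15.5, which is 0.539%, 2.08% and 2.49% of all germ barcodes. Summed over the cluster, EGR4 was 184 CPM, PIWIL4 187 CPM, NANOS2 66.0 CPM and SOHLH1, a marker on the fixed oocyte-like list, 243 CPM, against 1.30, 4.36, 2.12 and 4.35 CPM in the named germ cells. DAZL was 87.4 against 367 CPM, MKI67 46.1 against 240 CPM and POU5F1 31.8 against 305 CPM.

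Mouse cells, which the comparisons of germ cells do not use, held a cluster with UPK3B and LHX9 that made up 1.88%, 3.91% and 11.6% of mouse barcodes in E13.5, E14.5 and E15.5 (31, 28 and 206 barcodes). Mouse cells were gated as negative for both reporters and low in FSC-W. No explanation of this share, technical or biological, was tested.

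Early oogonia-like cells were a lower share of the named germ cells in E13.5 (13.4%) than in E14.5 and E15.5. A difference in depth among germ cells of at least 23000 UMIs is argued against: thinned to that depth, the shares were 14.2%, 26.4% and 25.6%. Shallower germ barcodes were not in this test. The shallow ones without a class were 24.1%, 4.84% and 17.04% of germ barcodes in E13.5, E14.5 and E15.5, so unequal loss of a class there stays open. Genes that differ between libraries steering the clustering are argued against too, since without the 58 genes past the size rule the shares were 13.47%, 25.8% and 24.2%. The sort, the culture, an unrecorded batch and the mouse stage cannot be told apart with 1 library per stage, and each may account for the share.

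The 18 genes at least 2-fold higher in germ cells of E14.5 than of E13.5 form 3 parts. For TKTL1 the lowest log2 ratio over 3 classes was 1.54, in early cells where it is near 0 CPM, and it was 3.77 in late and 3.15 in retinoic acid-responsive cells, so different shares of the classes are not the whole cause. Free mouse RNA would reach all germ classes alike, so the lowest of 3 classes in E14.5 bounds it. For 10 other genes, that lowest value had a median of 0.20 of the rise in pooled CPM (0.039 to 0.95). These 10 were picked as lower in mouse barcodes (median 1.21 against 44.7 CPM in germ cells). That choice itself left little room for free mouse RNA, so no conclusion on it is drawn from this test. The median log2 ratio of the 10 genes, 1.13, was 0.57 when averaged over classes. Of them 2 stayed at least 2-fold higher, so class shares may account for part of the rise. For LGALS1, ACTG2 and 5 other genes that mouse barcodes hold more of (median 1332 against 32.2 CPM), barcodes of both species are argued against, since the median was 1.24 and, without those barcodes, 1.30. Free mouse RNA is argued against for ACTG2, whose lowest class held 2.19 CPM, 0.0731 of its rise. For LGALS1 that share was 0.591, which leaves free mouse RNA open, and for the 5 others its median was 1.19, so free mouse RNA is a candidate explanation for them. Different shares of the classes were not tested for ACTG2. Its RNA was higher in early than in late or meiotic cells, and early cells were a larger share in E14.5, so class shares stay open for it. The mouse stage stays open for all 18 genes, untested.

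Of 14 replication-dependent histone genes at 20 CPM or more, 11 were lower in germ cells of E15.5 than of E13.5, with a median log2 ratio of -0.47, and 4 were at least 2-fold lower. Fewer germ cells in S phase is argued against by the S phase list, whose median log2 ratio averaged over 3 classes was 0.083. In mouse barcodes, 6 of 6 histone genes at that level were lower too, with a median of -0.94, while the median of 4 mouse S phase genes was 0.14. H1-3 and H2AC6, under that level in mouse barcodes, were higher there. Of 4 histone genes at that level in both species, 2 moved apart: H2AC25 was 73.5 and 102 CPM in germ cells and 544 and 440 CPM in mouse barcodes, and H2AC20 was 206 and 220 CPM and 121 and 110 CPM. A difference in library preparation, for example in the capture of histone RNA, most of which lacks a polyA tail, stays open, since it may account for lower genes but not for these 2. The mouse cells also differ in stage between the libraries, so a biological difference stays open, untested.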

How the results depend on the processing

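The shared-neighbour graph, the clustering without genes past the size rule, the removal of barcodes of both species, the inclusion of unnamed germ clusters and the totals without mitochondrial genes were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the groups share only replicate number 1. Where a value moved, the cause was not tested unless stated.

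The shares of the classes depended on the clustering. Values are for E13.5, E14.5 and E15.5. At resolution 0.6, late cells were 66.4%, 58.9% and 59.2%, retinoic acid-responsive cells 19.9%, 15.1% and 15.6%, and meiotic cells 0, 0 and 0. At resolution 1.5, late cells were 50.7% in E14.5 and 47.4% in E15.5, and retinoic acid-responsive cells 17.3% and 22.1%. With 4000 highly variable genes, late cells were 42.9% in E13.5, retinoic acid-responsive cells 43.2%, 28.4% and 36.6%, and meiotic cells 0 in each. With the gene lists kept in clustering, late cells were 34.2%, 31.9% and 30.9%, retinoic acid-responsive cells 48.4%, 39.6% and 43.9%, and early cells 19.6% in E15.5. With the shared-neighbour graph, late cells were 63.4%, 54.1% and 53.6%, retinoic acid-responsive cells 23.3% in E13.5 and 23.2% in E15.5, and meiotic cells 0 in each. Thinned to one depth, late cells were 54.0%, 52.7% and 45.4%, retinoic acid-responsive cells 15.8% in E14.5 and 23.3% in E15.5, and meiotic cells 3.69% in E13.5. The other 51 planned and 28 added values of the shares stayed within their intervals.

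The counts of genes at least 2-fold higher or lower in pooled germ cells depended on the rule. For E14.5 over E13.5, 18 higher genes became 28 with DESeq2 size factors, 11 with a pseudocount of 5 CPM, 54 with no minimum CPM, 11 with equal weight to each germ class and 28 with unnamed germ clusters included, and 18 lower genes became 49 with no minimum CPM. For E15.5 over E13.5, 5 higher genes became 3 with a pseudocount of 5 CPM, 31 with no minimum CPM and 0 with equal weight to each germ class, and 14 lower genes became 51 with no minimum CPM and 26 with the mean over cells. For E15.5 over E14.5, 10 higher genes became 6 with TMM factors, 6 with DESeq2 size factors, 5 with a pseudocount of 5 CPM, 34 with no minimum CPM and 6 with equal weight to each germ class, and 14 lower genes became 7 with a pseudocount of 5 CPM, 41 with no minimum CPM and 23 with unnamed germ clusters included. No minimum CPM admits more genes to the rule, and the equal weights leave out the meiotic class. Among the named genes, 253 planned and 106 added log2 ratios stayed past 2-fold or on their side of it, and 51 and 7 moved. With mitochondrial genes left out, ATP8 could give no value. Of the list medians, 137 were counted as kept and 6 as moved. A list away from both ends of the random lists in the main run counted as kept whatever the alternative gave. The 137 are therefore not a measure of stability. The pluripotency-associated list in E14.5 over E13.5 reversed, from 0.0044 to -0.084, with equal weight to each germ class.

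Between classes, 74 planned and 8 added counts of called genes stayed within 1.5 times the main count. For retinoic acid-responsive against late cells, 2542 higher and 2899 lower genes became 1582 and 1540 with no library block, and 1477 to 2222 and 1688 to 2686 without each library in turn, the lowest without the E13.5 library; fewer libraries leave fewer residual degrees of freedom. DESeq2 called 75.4% to 99.1% of the main calls, and testing with UMIs that the clustering had not used called 61.2% to 82.7% of them. The class names of that clustering still came from the main one, which had used all UMIs. Of the named fold changes, 743 planned and 75 added stayed called and 11 and 1 did not.

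Camera with the correlation estimated called 0 lists higher and 0 lower in each of the 4 contrasts. Leaving out each library in turn, fry called 1 to 2 lists higher in retinoic acid-responsive against late cells (5 with all libraries) and camera 3 to 6 (3). In meiotic against retinoic acid-responsive cells fry called 4 to 6 lists higher (7) and 3 to 7 lower (7), and camera 2 to 4 lower (2). In meiotic against early cells camera called 1 to 2 lists lower (1).

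Depth limits what can be seen in the meiotic class, which has the fewest cells of the named classes (35, 32 and 62). The median UMIs per barcode were 6529, 8892.5 and 6981 at a minimum of 500 UMIs and 7688, 12671 and 10844 at a minimum of 3000 UMIs.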

Other observations

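The test of the EGR4 and PIWIL4 cluster for male germline markers was written before its result was seen, from markers fixed beforehand, while the test of oocyte markers was chosen only after the cluster's values were seen, and the splits of the samples were run after the calls between classes were seen.

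The 50 cells led by EGR4 and PIWIL4 share genes with male germ cells near birth, so a hypothesis was that they are male germline-like. TSPAN33, PLPPR3, MSL3, PHGDH, CDK17, RGS14 and FGFR3 served as 7 further markers of such cells. Their median log2 ratio of the cluster over the named germ cells was 2.46, at percentile 100 of matched random lists, whose median was 0.05. TSPAN33 was 80.7 against 2.97 CPM, RGS14 72.2 against 6.53 CPM, PLPPR3 27.5 against 1.91 CPM, MSL3 542 against 97.6 CPM and PHGDH 123 against 42.9 CPM, while CDK17 was 164 against 60.7 CPM and FGFR3 145.3 against 90.03 CPM. The fixed list of oocyte markers, which holds SOHLH1, passed the same test: 8 of its 10 markers were highest in this cluster, and 9 at 1 CPM or more had a median log2 ratio of 2.31, at percentile 99.9 (1.91 and 99.1 without SOHLH1). The results are consistent with male germline-like or with oocyte-like expression and do not separate the 2. The cluster was found on the same cells, markers may be among the genes that formed it, and the default graph of scanpy, looked at first, did not separate it. SYCP3 was 36.6 against 179 CPM and STRA8 8.55 against 33.0 CPM, while 1 of 9 fixed meiotic markers was highest in this cluster. DDX4 was 142 against 119 CPM. The sort kept cells positive for either reporter and would not remove such cells.

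Shallow germ barcodes without a class, with a median of 1455 UMIs, made up 24.1%, 4.84% and 17.04% of germ barcodes in E13.5, E14.5 and E15.5. Genes that led this cluster included INHA at 326 CPM and LOC102140619 at 382 CPM. The largest supporting cell cluster held 3127 CPM of INHA, and mouse barcodes of E14.5 held 1818 CPM of LOC102140619. DAZL was 329 CPM in the shallow barcodes, so RNA of germ and of mouse cells may both be in them. A mouse cluster led by AMH, with INHA among its leading genes, made up 33.6%, 40.1% and 17.9% of mouse barcodes. An unnamed one with supporting and stromal genes, also with AMH among its leading genes, made up 1.88%, 6.01% and 2.30%, and one with LTF and EHF 0.424%, 5.45% and 0.956%. The mitochondrial share of germ UMIs in E13.5, E14.5 and E15.5 was 7.13%, 7.13% and 9.30% in early oogonia-like, 6.49%, 6.68% and 8.70% in late oogonia-like, 7.60%, 7.60% and 9.66% in retinoic acid-responsive-like and 6.98%, 7.66% and 8.75% in meiotic-like cells.

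The 6 sums of a contrast between classes can be split in 10 ways, which is too few for a share under 0.05. The real split, 1 of the 10, called 9228 genes for late against early, 5441 for retinoic acid-responsive against late, 7595 for meiotic against retinoic acid-responsive and 10271 for meiotic against early cells, and the highest of the other splits called 0 in each. Every other split mixes both classes in each group, so the class difference adds to its spread and few calls could arise. The classes were also made from these same cells, so the splits do not test how the classes arose.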
